A study of Mus musculus with 6 samples.

How the data were processed

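Liver RNA of 6 female C57BL/6 mice, 3 months old and kept without food for 6 h before they were killed, was hybridised to 1-colour microarrays, with 1 array per mouse. There were 3 mice homozygous for the Lmna G609G knock-in allele and 3 wild-type mice. Per the labels' protocols, RNA was isolated on RNeasy columns, copied into double-stranded cDNA with a SuperScript kit, and labelled with biotin by in vitro transcription. The authors' deposited table held 1 intensity per probe set and array, on a linear scale and in whole numbers, for 35512 probe sets. How the authors summarised the probes, corrected the background and normalized the arrays is not given in the sources used here. Scanner files and detection calls were not used here.

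The 6 columns were matched to the mice by the sample identifiers in the header. Array medians lay between 97.0 and 104 intensity units, a range of 0.087 on the log2 scale, which was below the limit of 0.1 set for further scaling, so the values entered the fit as deposited. An exact two-sided permutation test of the array medians between the genotypes gave p = 0.20, for which 3 mice against 3 allow no p below 0.1. No 2 arrays held identical values. Xist lay between 7159 and 8720 on all 6 arrays, and the Y-linked genes Eif2s3y, Kdm5d and Uty lay at 34.0 or less, as the sex on the labels implies. Arrays carry no read depth, and their number (3 per genotype) limits the precision. Probe sets were named through the platform annotation, which can be old. Of all probe sets, 21789 had 1 gene symbol, 1621 had several and 12102 were not listed, and the named ones covered 19938 genes. Symbols were compared with the RefSeq annotation of GRCm38.p6 through gene identifiers and 0 differed. The genome build of the probe sets is not given in the sources used here, so no coordinates are reported. Control probe sets could not be told apart by name and stayed in the table. The 3 prime to 5 prime signal ratio of control transcripts, a sign of RNA quality, was not analysed here for the same reason.

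Intensities were transformed as log2(value + 16), so fold changes are on that scale and understate the change of dim genes. Probe sets whose mean over the 6 arrays lay under the 25th percentile were left out, and 26634 were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) as knock-in minus wild-type, with Benjamini-Hochberg adjustment over probe sets and a threshold of 0.05. A probe set was called changed when its adjusted p was below that threshold. Errors of log2 changes are standard errors, and errors of intensities are standard deviations over 3 mice. Each gene of a list was represented by its probe set with the highest mean. A total of 36 gene lists (25 pathway lists and 11 lists of cell type markers) were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Of 1096 list members, 974 were matched to a probe set with 1 gene.

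The named genes are Lmna, the 15 genes with the largest rise and the 15 with the largest fall among called probe sets with 1 gene symbol, no overlap between the genotypes and a higher-group mean at or above the median of all probe sets, and members of the lists, up to 4 by smallest p together with any that passed. Genes with clone names were left out of the 30. The lists, the rule and the alternatives were fixed before the data were examined, apart from a fit on probe sets with exactly 1 gene, which was chosen after seeing the data. The other alternatives were pseudocounts of 1 and 64, quantile normalization, arrays centred on their medians, no filter and a filter at the 50th percentile, eBayes without trend and with a robust prior, array weights, 1 probe set per gene or their mean, thresholds of 0.1 or of 1.5-fold, and each mouse left out in turn.

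The procedure was tested on simulated data with the knock-in against wild-type layout over 26634 probe sets. It recovered 29.8% of simulated log2 changes of 0.5, 77.8% of changes of 1, 97.7% of changes of 2 and 100% of changes of 4, and 6.12% of its calls were false. A list shifted by -1 was found, and 0 of the 35 other lists were called. The simulated probe sets varied independently of each other, so this does not show how the list test behaves when the genes of a list are correlated. Besides the shifted list, only 38 to 47 tested probe sets were changed at each size, while 25.9% were called in the real data. Adjustment is stricter where few probe sets change, so the recovery rates are not those of the real comparison. Figures were drawn with matplotlib 3.10.9.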

Results

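The series measured gene expression in the liver of mice carrying the G609G allele of Lmna, the gene of the nuclear envelope proteins lamin A and lamin C. The allele is a point change that leaves the encoded amino acid as it was and alters splicing of the transcript, and mice homozygous for it are a model of Hutchinson-Gilford progeria, a premature ageing syndrome. The data were intensities of 35512 probe sets on 6 arrays, from 3 knock-in mice (replicates 1, 3 and 5) and 3 wild-type mice (replicates 2, 4 and 6), all female, 3 months old and without food for 6 h. Array intensities ran from 7 to between 23345 and 24988, with medians between 97.0 and 104. Each array came from a separate animal by its label, so the limma p-values below measure the spread between mice, with 3 mice per genotype throughout. Camera p-values at the preset correlation compare the members of a list with other genes and treat the members as nearly independent.

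The comparison asked which liver transcripts differ between knock-in and wild-type mice. Genes such as Sult1e1, Ddit4, Btg2, Gadd45g and Igfbp1 were 8.69-fold to 35.3-fold higher, while metabolic genes such as Dio1, Car3, Fabp1 and Bdh1 were 12.1-fold to 24.5-fold lower. Lists of glucocorticoid-induced and ribosomal protein genes rose, and lists of interferon response, fatty acid oxidation, cholesterol synthesis and lipogenic genes fell, by camera with a preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.504 to 0.567). Of 26634 probe sets tested, 6888 (25.9%) were called by limma at a Benjamini-Hochberg adjusted p below 0.05, with 3974 higher and 2914 lower in knock-in liver, and 10059 had an unadjusted p below 0.05. Of the calls, 715 were at least 2-fold higher and 724 at least 2-fold lower. Of the calls, 4720 had 1 gene symbol, 344 had several and 1824 had no listed gene, and the last may include control probe sets. The called probe sets covered 2132 genes with a higher and 2243 genes with a lower probe set. Only Hmcn1 and Tpm3, named here after their values were seen, had probe sets called in both directions. The genotypes did not overlap at 41.1% of tested probe sets, where chance gives 10%. The share of calls that were higher was 57.7%, and 47.7% (3119 higher, 3424 lower) once each array was centred on its median. Without knock-in replicate 1, 4236 probe sets were called, without wild-type replicate 2 4478, and without wild-type replicate 6 4564.

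Lmna itself showed no called difference in total signal. Its probe set (10499394) read 290, 249 and 258 in the knock-in mice and 282, 267 and 362 in the wild-type mice, a log2 change of -0.17 ± 0.13 (SE, n = 3 mice per genotype; limma adjusted p = 0.40; 95% interval -0.48 to 0.14). The probe set gives 1 value for the gene, so it does not separate normally from aberrantly spliced transcripts and does not check the genotype.

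The arrays separated by genotype. The first principal component held 75% of the variance, with knock-in mice at 46.1, 24.3 and 52.1 and wild-type mice at -44.7, -38.8 and -38.9. Correlations across probe sets, which are not independent, were 0.988 to 0.993 within knock-in, 0.992 to 0.995 within wild-type and 0.960 to 0.980 between the genotypes. Knock-in replicate 3 was the knock-in array nearest to wild-type, with correlations of 0.976 to 0.980 to the wild-type arrays against 0.960 to 0.969 for the other knock-in arrays.

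The largest rise was that of Sult1e1, which encodes the estrogen sulfotransferase. It read 36 ± 5.29 in wild-type and 1873 ± 571 in knock-in liver, a log2 change of 5.14 ± 0.22 (35.3-fold; limma adjusted p = 5.46e-05). Ddit4, a stress-induced inhibitor of mTOR signalling, rose 15.2-fold, from 315 ± 124 to 4774 ± 857. Cyp26a1, which breaks down retinoic acid, rose 14.8-fold, from 173 ± 58.0 to 2725 ± 560. The anion exchanger gene Slc4a9 and the antiproliferative gene Btg2 both rose 13.5-fold, and the nuclear receptor gene Nr4a1 rose 12.5-fold. Phf11c and its neighbour Setdb2, which encodes a SET domain protein, rose 12.1-fold and 8.75-fold. Wild-type replicate 6 read 1088 and 1518 where the other wild-type mice lay at 477 or below, and without it the log2 changes were 4.21 and 3.74. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose 11.8-fold, and the growth arrest gene Gadd45g rose 11.1-fold. The clock gene Arntl rose 9.59-fold and the transcriptional repressor gene Nfil3 rose 8.77-fold. Igfbp1, a binding protein of insulin-like growth factors, rose 8.69-fold to 13118 ± 873, among the brightest signals named. Mpzl1 rose 8.89-fold and Fam107a rose 8.59-fold.

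Dio1, a deiodinase that activates thyroid hormone, fell from 2061 ± 230 in wild-type to 72.3 ± 33.5 in knock-in liver, a log2 change of -4.61 ± 0.24 (24.5-fold lower; limma adjusted p = 0.000109). Car3, a carbonic anhydrase, fell from 11593 ± 537 to 908 ± 1020, and Fabp1, the main fatty acid binding protein of hepatocytes, fell from 9686 ± 1366 to 858 ± 1026. Serpina6, which encodes corticosteroid-binding globulin, was 10.8-fold lower. Inhbe, an inhibin subunit gene, fell from 1055 ± 243 to 49.7 ± 1.53. Bdh1, which interconverts ketone bodies, was 12.1-fold lower, and Ccnd1, a cyclin of cell cycle entry, was 11.4-fold lower. The endothelial lipase gene Lipg and Keg1 were 10.6-fold and 10.9-fold lower. Among members of large gene families, Sult2a8 was 23.6-fold, Cyp2d37-ps 14.1-fold, Mup3 13.8-fold, Nat8f2 12.3-fold, Ces1f 11.6-fold and Serpina4-ps1 10.8-fold lower. Probes of these and of Phf11c may hybridise with close paralogs, so which family member changed is uncertain. A gene with a clone name, Gm21286 (named after its values were seen), passed the same criteria with a log2 change of -6.46 ± 0.22. Knock-in replicate 3 read 2043 for Fabp1 and 2086 for Car3, where the other knock-in mice lay at 340 or below. Without it the log2 changes were -5.09 for Fabp1, -5.12 for Car3, -5.32 for Sult2a8, -4.42 for Ces1f, -4.10 for Serpina6 and -4.04 for Keg1. Without wild-type replicate 4, that of Serpina4-ps1 was -4.13. With a pseudocount of 64, the log2 changes were 4.23 for Sult1e1, -3.98 for Dio1, -3.28 for Inhbe, -3.74 for Sult2a8 and -2.79 for Serpina4-ps1.

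**Figure D1:**
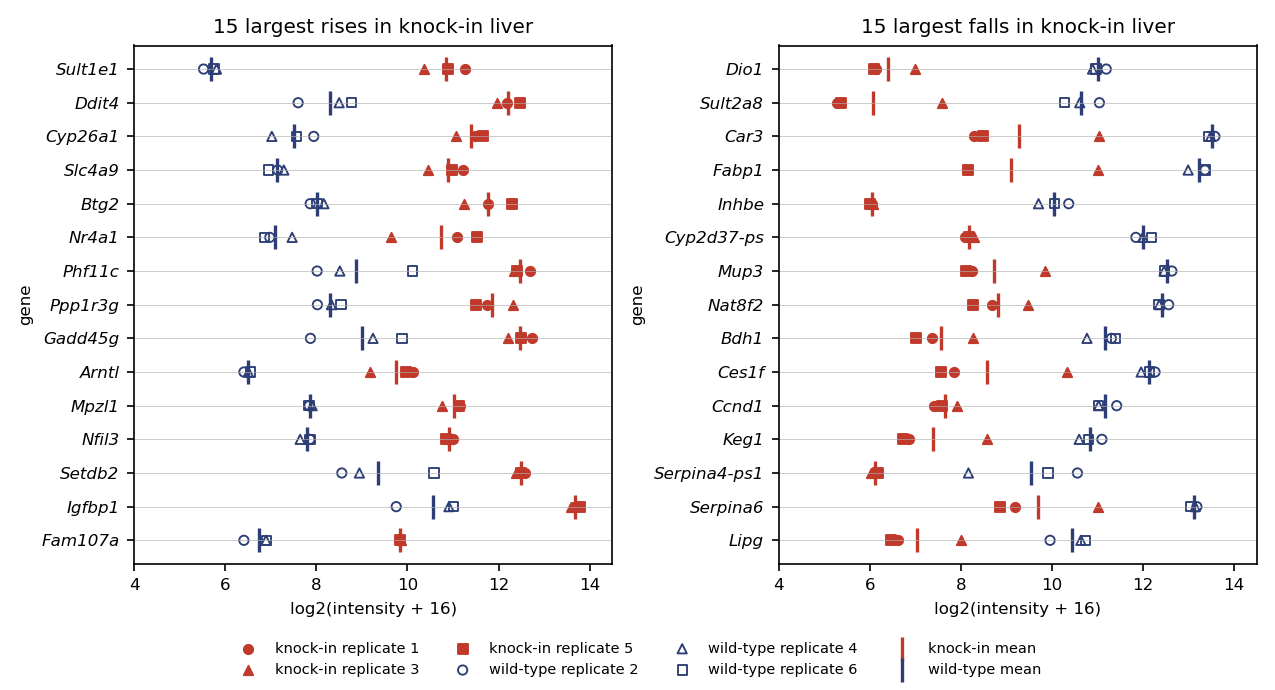
Intensity of the 15 genes with the largest rise and the 15 with the largest fall in knock-in liver, as log2(intensity + 16) on the x axis, with 1 symbol per mouse (filled red, knock-in; open blue, wild-type) and a vertical bar at each genotype's mean. The genotypes do not overlap at any of the 30 genes, and knock-in replicate 3 lies toward wild-type at Fabp1 (2043) and Car3 (2086) and not at Inhbe (51).

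Genes that glucocorticoids induce rose together. Of 23 measured, 19 rose, 0 fell and 4 did not pass (19 and 0 adjusted over the list alone), with a median log2 change of 1.20 (2.29-fold; camera adjusted p = 4.35e-11, and adjusted p = 0.504 with an estimated correlation). Besides Sult1e1, Ddit4 and Igfbp1, the kinase gene Sgk1 rose 7.22-fold and the glucocorticoid receptor co-chaperone gene Fkbp5 rose 2.29-fold. Of the 23 members, 15 are also in other lists. Among p53 target genes, 13 of 29 rose and 4 fell (13 and 5 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.00593, and adjusted p = 0.504 with an estimated correlation). The members that rose included Sesn1 (log2 change 2.91 ± 0.17), Btg2, Ddit4 and Gadd45b (log2 change 3.07 ± 0.28), all of which also respond to other stress signals. Among the 4 that fell were Perp (log2 change -1.03 ± 0.18) and Ccng1 (log2 change -0.39 ± 0.09). The listed genes Cdkn1a, Bax and Eda2r had no tested probe set with 1 gene and are not among the 29. Phlda3, Aen and Pmaip1, named here after their values were seen, did not pass (limma adjusted p = 0.984, 0.524 and 0.848). Genes of the acute phase response, the liver's response to inflammation, rose in 12 and fell in 2 of 33 cases (15 and 2 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.00306, and adjusted p = 0.567 with an estimated correlation). Orm3 rose by a log2 change of 2.98 ± 0.24, Cebpd by 1.93 ± 0.14, Socs3 by 1.59 ± 0.17 and Lbp by 0.79 ± 0.07. Saa4, 1 of the 2 that fell, changed by -1.79 ± 0.21. Without knock-in replicate 5 the median of this list was 0.34, and 5 members fell without knock-in replicate 3. Neutrophil markers moved in the same direction, with 5 of 11 higher, 0 lower (6 and 0 adjusted over the list alone) and a median of 0.24 (camera adjusted p = 0.00169, and adjusted p = 0.504 with an estimated correlation). Of these, Lcn2 (log2 change 2.01 ± 0.24) is also an acute phase gene, and Retnlg, S100a8, Il1r2 and Mmp9 had means of 93.3 or less in both genotypes. The call of Mmp9 was lost without knock-in replicate 1 or 5 or wild-type replicate 2 or 4 (adjusted p = 0.0510 to 0.0576). Without wild-type replicate 2 the median of the neutrophil markers was 0.37.

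Most of the measured genes of fat oxidation, lipogenesis and cholesterol synthesis fell. Of 41 genes of fatty acid oxidation and ketogenesis, 29 fell, 1 rose and 11 did not pass (32 and 1 adjusted over the list alone), with a median log2 change of -1.02 (2.03-fold lower; camera adjusted p = 6.28e-10, and adjusted p = 0.567 with an estimated correlation). Besides Fabp1 and Bdh1, the lipid droplet gene Plin2 changed by -3.15 ± 0.30 and Ppara, the nuclear receptor that drives these genes, by -1.56 ± 0.19. Without knock-in replicate 1, 18 of the 41 fell. The one that rose was Pdk4 (3.18-fold), which restrains the entry of pyruvate into the citric acid cycle. Among 32 genes of glycolysis and lipogenesis, 19 fell and 2 rose (21 and 3 adjusted over the list alone), with a median of -0.68 (camera adjusted p = 1.07e-05, and adjusted p = 0.567 with an estimated correlation). Fatty acid synthase, Fasn, changed by -1.85 ± 0.21, the carboxylase gene Acaca by -1.63 ± 0.19 and the elongase gene Elovl6 by -2.91 ± 0.41. Only 1 rose without knock-in replicate 1 or 5 or wild-type replicate 4. Among 21 genes of cholesterol synthesis, 16 fell and 1 rose (16 and 1 adjusted over the list alone), with a median of -1.21 (2.32-fold lower; camera adjusted p = 2.10e-06, and adjusted p = 0.567 with an estimated correlation). Hmgcs1 changed by -2.55 ± 0.17, Idi1 by -2.69 ± 0.35 and Msmo1 by -2.36 ± 0.21, while Insig2, which restrains this pathway, rose by 1.87 ± 0.15. The number that fell was 8 without knock-in replicate 1, 10 without knock-in replicate 5 and 9 without wild-type replicate 4, where 2 rose. Of 28 genes of bile acid synthesis and transport, 13 fell and 5 rose (15 and 5 adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.0211, and adjusted p = 0.567 with an estimated correlation). Hsd3b7 and the bile acid receptor gene Nr1h4 changed by -2.03 ± 0.14 and -1.51 ± 0.24, and the transporter gene Slco1a4 rose by 1.13 ± 0.11. The number that rose was 3 without knock-in replicate 1 or wild-type replicate 4 or 6. This list's call was lost with quantile normalization (adjusted p = 0.105), with centred arrays (adjusted p = 0.0772) and with the filter at the 50th percentile (adjusted p = 0.0605). Of 25 genes of gluconeogenesis and glycogen, 11 rose and 8 fell (12 and 9 adjusted over the list alone), with no called shift of the list (median 0.13, camera adjusted p = 0.395). Ppargc1a, a coactivator of gluconeogenesis, rose by 2.30 ± 0.18.

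Interferon response genes were lower in knock-in liver. Of 36 measured, 27 fell, 0 rose and 9 did not pass (28 and 0 adjusted over the list alone), with a median log2 change of -1.04 (2.06-fold lower; camera adjusted p = 1.22e-12, and adjusted p = 0.504 with an estimated correlation). Ifit1 changed by -1.75 ± 0.09, Oas2 by -1.03 ± 0.09, and the transcription factor genes Stat2 and Irf9 by -1.59 ± 0.15 and -1.30 ± 0.13. Markers of immune cells were measured in the same arrays. Of 20 markers of Kupffer cells and macrophages, 3 fell and 0 rose (2 and 0 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 0.0617). The median was -0.15 without knock-in replicate 5, -0.10 without wild-type replicate 2 and -0.46 without wild-type replicate 6. That list was called without knock-in replicate 1 (adjusted p = 0.0133), without knock-in replicate 3 (adjusted p = 0.0218), without wild-type replicate 6 (adjusted p = 0.00189) and with no filter (adjusted p = 0.0342). With an estimated correlation it was not called (adjusted p = 0.714 over all mice, and adjusted p = 0.622 to 0.678 without those mice). Without knock-in replicate 5, 2 of the markers rose, and without knock-in replicate 3, 5 fell. The 3 that fell over all mice were Aif1, Slc40a1 and Adgre1, and each call was lost with single mice left out. That of Aif1 was lost without knock-in replicate 1 or 5 (adjusted p = 0.0520 to 0.0629), that of Slc40a1 without knock-in replicate 1 or wild-type replicate 2 or 6 (adjusted p = 0.0552 to 0.0662), and that of Adgre1 without knock-in replicate 1 or 5 or wild-type replicate 2 or 4 (adjusted p = 0.0865 to 0.127). Adgre1 was also lost with no filter (adjusted p = 0.0744), a robust prior (adjusted p = 0.0503) and array weights (adjusted p = 0.0640). Of 15 lymphocyte markers, Cd79b fell and the others did not pass (0 higher and 1 lower adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0322, and adjusted p = 0.567 with an estimated correlation). That call was lost without knock-in replicate 5 (adjusted p = 0.0718), without wild-type replicate 4 (adjusted p = 0.0714), with the filter at the 50th percentile (adjusted p = 0.854), with eBayes without trend (adjusted p = 0.0595) and on probe sets with exactly 1 gene (adjusted p = 0.0720). Without knock-in replicate 3, 2 of the lymphocyte markers fell. Among NF-kappaB and inflammatory targets, 7 of 37 rose and 6 fell (8 and 6 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.395), and 3 fell without knock-in replicate 1. The median was 0.09 without knock-in replicate 5, 0.07 without wild-type replicate 6 and 0.06 without wild-type replicate 2. Cd14 rose by 1.55 ± 0.11, and the interferon-inducible chemokine gene Cxcl9 changed by -2.65 ± 0.28.

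Genes that are higher in male than in female liver were mostly lower in knock-in liver. Of 23 measured, 15 fell and 1 rose in these females (17 and 2 adjusted over the list alone), with a median log2 change of -0.89 (camera adjusted p = 5.35e-06, and adjusted p = 0.504 with an estimated correlation). They included Nudt7 (-3.03 ± 0.30), Cyp7b1 (-2.05 ± 0.29) and Mup3. Of 24 genes that are higher in female liver, 9 fell and 3 rose (11 and 5 adjusted over the list alone), with a median of -0.65 that did not pass (camera adjusted p = 0.0842). This list was called without knock-in replicate 3 (adjusted p = 0.0430) and without wild-type replicate 2 (adjusted p = 0.0184). With an estimated correlation it was not called (adjusted p = 0.567 over all mice, and adjusted p = 0.395 and 0.562 without those mice). The 3 that rose were Sult1e1, Tox (1.07 ± 0.11) and Cyp2b10 (2.08 ± 0.25). The somatotroph list was not called (5 of 17 higher, 6 lower, 6 and 6 adjusted over the list alone, median -0.11, mean 0.12, camera adjusted p = 0.955). This list had a median of -0.03 without knock-in replicate 1. Without wild-type replicate 2 it had a median of -0.06, and its test pointed to higher (camera adjusted p = 0.618). Within it the growth hormone receptor gene Ghr changed by -1.52 ± 0.27 and Igfals, which stabilises circulating insulin-like growth factor, by -2.40 ± 0.19, while Socs2, a brake on growth hormone signalling, rose by 1.89 ± 0.28. Igf1 changed by -0.11 ± 0.07 and did not pass (limma adjusted p = 0.357; named after its values were seen).

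Detoxification genes fell more often than they rose. Of 33 NRF2 target and glutathione genes, 17 fell and 2 rose (21 and 2 adjusted over the list alone), with a median log2 change of -0.54 (camera adjusted p = 8.55e-06, and adjusted p = 0.567 with an estimated correlation). Nfe2l2, which encodes NRF2, changed by -1.69 ± 0.14, catalase (Cat) by -1.11 ± 0.14 and Gstm2 by -0.99 ± 0.10, and the 2 that rose were Abcc4 (1.70 ± 0.28) and Hmox1 (1.44 ± 0.25). Without knock-in replicate 1 or wild-type replicate 2, 11 of them fell. Xenobiotic metabolism genes fell in 13 and rose in 7 of 32 cases (14 and 7 adjusted over the list alone), and the list's median of -0.23 did not pass (camera adjusted p = 0.137) except without knock-in replicate 3 (adjusted p = 0.0164, and adjusted p = 0.398 with an estimated correlation). The median was -0.35 without that mouse and -0.14 without knock-in replicate 5. Without wild-type replicate 2, 8 fell and 4 rose, and 3 and 4 rose without knock-in replicate 1 and wild-type replicate 4. The receptor gene Nr1i3 changed by -1.52 ± 0.09 and Cyp1a2 by -2.36 ± 0.41. Of 52 ribosomal protein genes, 26 rose and 0 fell (32 and 0 adjusted over the list alone), by a small median log2 change of 0.30 (1.23-fold; camera adjusted p = 3.75e-09, and adjusted p = 0.504 with an estimated correlation). Rpl9 and Rps28 both rose by 0.54, with errors of 0.08 and 0.09. Leaving out any mouse but knock-in replicate 3 brought the number that rose to between 11 and 17. Of 68 genes of oxidative phosphorylation, 20 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.28 (camera adjusted p = 2.10e-06, and adjusted p = 0.567 with an estimated correlation), among them Ndufs8 (-0.77 ± 0.12) and Ndufb3 (-0.50 ± 0.08). The number that fell was 33 without knock-in replicate 3, 5 and 13 without knock-in replicates 1 and 5, and 7 and 6 without wild-type replicates 2 and 6.

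Clock genes changed in both directions. Of 23 genes of the circadian clock and its outputs, 10 rose and 6 fell (10 and 8 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.359). Its median log2 change was 0.10, and it was 0.04 without knock-in replicate 1, -0.00509 without wild-type replicate 2, 0.23 without wild-type replicate 4 and 0.30 without wild-type replicate 6. Arntl and Nfil3 rose most, Cry1 rose by 1.70 ± 0.12, Cry2 by 1.59 ± 0.14 and Clock by 0.67 ± 0.12. Dbp changed by -2.52 ± 0.15, Per3 by -2.29 ± 0.18, Wee1 by -2.01 ± 0.22 and Hlf by -1.18 ± 0.15, while Per1 rose by 1.15 ± 0.22. Nr1d1 changed by -0.46 ± 0.18 and did not pass (limma adjusted p = 0.106; named after its values were seen). The labels give no time of day for any mouse.

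**Figure D2:**
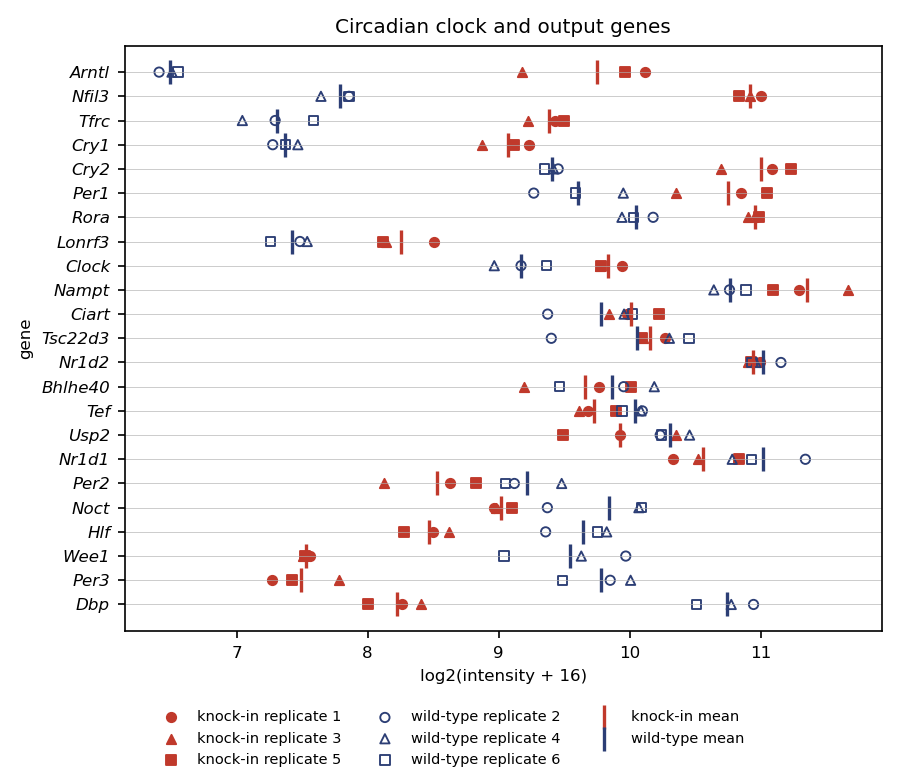
Intensity of the 23 measured genes of the circadian clock and its outputs, as log2(intensity + 16) on the x axis, sorted by log2 change, with 1 symbol per mouse (filled red, knock-in; open blue, wild-type) and a vertical bar at each genotype's mean. Arntl, Nfil3 and Cry1 are higher in all 3 knock-in mice than in any wild-type mouse, and Dbp, Per3 and Wee1 are lower in all 3.

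The stress, nuclear and growth lists held changed genes in both directions without a called shift of the list. Of 31 genes of the nuclear lamina and envelope, 10 rose and 4 fell (12 and 8 adjusted over the list alone; median log2 change 0.03, camera adjusted p = 0.409). Those that rose included the inner nuclear membrane genes Emd (1.05 ± 0.11), Sun1 (1.06 ± 0.17) and Sun2 (0.80 ± 0.13). Of 34 genes of the DNA damage response and repair, 5 rose and 4 fell (5 and 4 adjusted over the list alone; median -0.07, mean 0.06, camera adjusted p = 0.795). The checkpoint kinase gene Chek1 rose by 1.71 ± 0.12 and the helicase gene Blm by 1.79 ± 0.16, while Parp1 changed by -0.63 ± 0.11. Among 35 cell cycle genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone; median -0.10, camera adjusted p = 0.173), and apart from Ccnd1 the called changes were under 2-fold. Of 38 genes of the unfolded protein and integrated stress response, 10 rose and 4 fell (12 and 6 adjusted over the list alone; median 0.00279, camera adjusted p = 0.504), including Sesn2 (1.94 ± 0.24) and Chac1 (1.27 ± 0.18). Of 36 autophagy and lysosome genes, 14 rose and 4 fell (14 and 6 adjusted over the list alone; median 0.01, camera adjusted p = 0.359), including Map1lc3b (0.86 ± 0.11) and Ctsl (1.15 ± 0.16). Of 24 heat shock chaperone genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone; median -0.15, camera adjusted p = 0.137). Of 33 genes of the extracellular matrix and fibrosis, 3 rose and 3 fell (1 and 1 adjusted over the list alone; median -0.08, camera adjusted p = 0.40). These counts depended on single mice. In the nuclear lamina list 6 rose without knock-in replicate 1 or wild-type replicate 4 or 6. In the DNA damage list 3 rose without knock-in replicate 1 or wild-type replicate 2 or 6, 1 fell without knock-in replicate 5 or wild-type replicate 2 or 6, and 2 fell without wild-type replicate 4. In the unfolded protein list 5 rose and 1 fell without knock-in replicate 1 or wild-type replicate 2, 6 rose and 2 fell without knock-in replicate 5, 2 fell without wild-type replicate 4 or 6, and 9 fell without knock-in replicate 3. In the autophagy list 9 rose without knock-in replicate 1, 2 fell without knock-in replicate 1 or wild-type replicate 2 or 6, and 7 fell without knock-in replicate 3. Of the chaperone genes 3 fell without wild-type replicate 6. Without knock-in replicate 1 the median was -0.09 for the chaperone genes and -0.05 for the cell cycle genes. In the matrix list 1 rose without knock-in replicate 1 or any wild-type mouse, 1 fell without knock-in replicate 1 or 5 or wild-type replicate 2 or 6, and 5 fell without knock-in replicate 3. The medians of the lamina list (without wild-type replicate 2), the unfolded protein list (without knock-in replicate 1 or wild-type replicate 2 or 4) and the autophagy list (without knock-in replicate 3 or wild-type replicate 6) changed sign.

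Markers of the cell types of the liver, and of tissues that could be dissected with it, were tested in the same way. Hepatocyte identity genes had a median log2 change of -0.07, with 3 of 24 higher and 6 lower (4 and 7 adjusted over the list alone, camera adjusted p = 0.342). That median was -0.11 without wild-type replicate 4 and -0.05 without wild-type replicate 6. The transcription factor gene Hnf4a rose by 0.84 ± 0.09, and Cebpa changed by -1.02 ± 0.13. Endothelial markers rose in 4 and fell in 6 of 21 cases (4 and 8 adjusted over the list alone; median -0.20, camera adjusted p = 0.387), and 2 fell without knock-in replicate 1 or wild-type replicate 2 and 1 without wild-type replicate 6. The number that rose was 2 without any one mouse but knock-in replicate 3, and the median was -0.10 without knock-in replicate 1. Stellate cell markers rose in 1 (Dcn) and fell in 3 (Lrat, Ngfr and Colec11) of 17 cases (1 and 4 adjusted over the list alone, median -0.11, camera adjusted p = 0.203). Their median was -0.21 without knock-in replicate 3 and -0.05 without wild-type replicate 2. The call of Colec11 was lost without knock-in replicate 1 or 5 or wild-type replicate 2 or 6 (adjusted p = 0.0692 to 0.0804), and 5 of the list fell without knock-in replicate 3. Of 12 cholangiocyte markers only Anxa4 passed, and it was lower (0 and 1 adjusted over the list alone; median 0.03, camera adjusted p = 0.851). Of 11 erythroid markers, Slc25a37, Car1, Alas2 and Car2 fell and 0 rose (0 and 4 adjusted over the list alone; median 0.02, camera adjusted p = 0.395). Single mice left out ended the calls of Car1 (without wild-type replicate 2 or 4, adjusted p = 0.0539 to 0.0555), Alas2 (without wild-type replicate 2 or 6, adjusted p = 0.0610 to 0.0675) and Car2 (without each mouse but wild-type replicate 4, adjusted p = 0.0507 to 0.111). The median of the cholangiocyte and erythroid lists is above 0 and their mean and test point below. It fell under 0 for cholangiocytes without knock-in replicate 1 and for the erythroid list without knock-in replicate 3 or wild-type replicate 2. Of 8 adipocyte markers, Fabp4 rose and Car3, abundant in liver too, fell (2 and 1 adjusted over the list alone, median 0.07, mean -0.25, camera adjusted p = 0.624). The call of Fabp4 was lost without wild-type replicate 2 or 4 (adjusted p = 0.0713 to 0.0750). The adipocyte median was 0.13 without knock-in replicate 1, 0.11 without wild-type replicate 4 and 0.03 without knock-in replicate 5 or wild-type replicate 2. Without knock-in replicate 3, 2 of these markers rose. Of 14 skeletal muscle markers, Atp2a1 rose by 0.40 ± 0.08 (1 and 0 adjusted over the list alone; median 0.05, camera adjusted p = 0.359), and of 11 pancreas acinar markers 0 passed (0 and 0 adjusted over the list alone; median 0.09, camera adjusted p = 0.624).

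Of the 36 lists, 5 were called higher and 9 lower by camera with the preset correlation of 0.01, and 0 were called with a correlation estimated for each list, where the lowest adjusted p was 0.504. By fry, which tests whether the members of a list move on balance one way and does not compare them with other genes, 10 lists were higher and 11 lower.

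**Figure D3:**
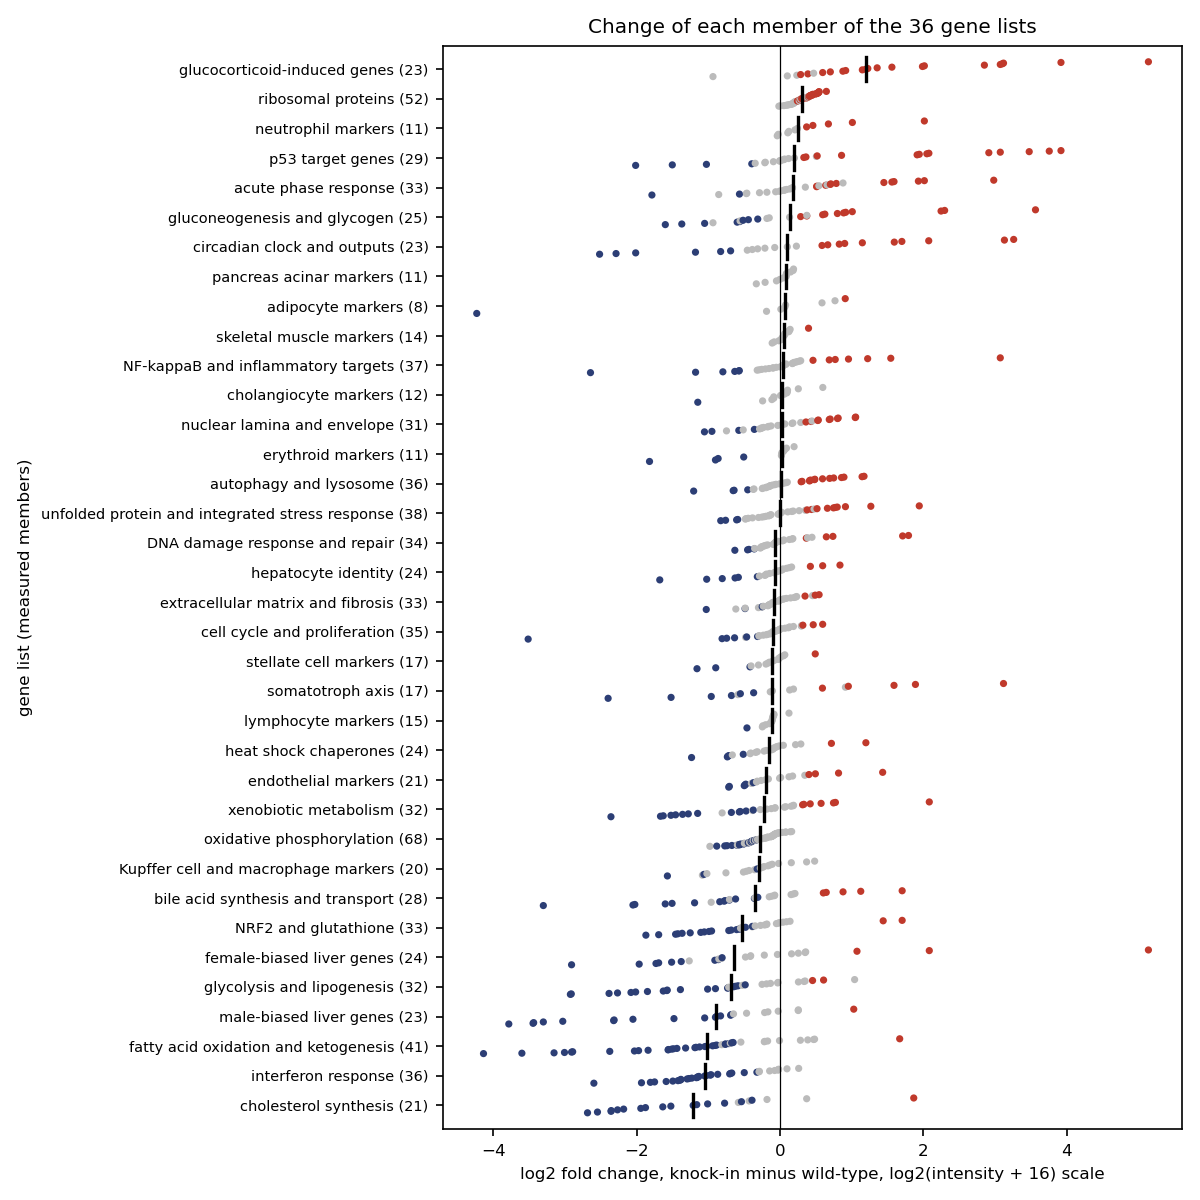
Log2 change, knock-in minus wild-type, of every measured member of the 36 gene lists, with the number of members in brackets and lists sorted by their median (black bar). Red and blue points are members called higher and lower, and grey points did not pass. The medians run from -1.21 for cholesterol synthesis to 1.20 for glucocorticoid-induced genes.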

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

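Of the 6888 calls, 0 were called in the other direction under any setting that tests probe sets, and the 30 genes with the largest changes stayed called with each mouse left out in turn. The total stayed within 1.5 times of 6888 under other pseudocounts, scalings, filters and variance models (6317 with no filter to 8636 with array weights). Requiring at least 1.5-fold left 3851 calls, 2077 higher and 1774 lower, by construction. Higher calls fell to 2320 with 1 probe set per gene, to 2318 with the mean per gene and to 2643 on probe sets with exactly 1 gene, a fit chosen after seeing the data. Lower calls were 2508, 2510 and 2626, which puts the share of calls that were higher at 48.1%, 48.0% and 50.2% against 57.7%. These fits test fewer features and leave out the probe sets with several genes or no listed gene. In the main fit the genes with a called probe set were 2132 higher and 2243 lower. The excess of higher calls thus did not hold over named genes. With 1 mouse left out, calls ranged from 4236 to 7725, higher calls from 2422 to 4271 and lower calls from 1814 to 3454. The lists called ranged from 13 to 17, with 5 higher each time and 8 to 12 lower, and the log2 change of Lmna from -0.26 to -0.05 without passing. Camera with an estimated correlation called 0 lists, 0 higher and 0 lower. It differs from the main run in the correlation between genes and in its degrees of freedom. These follow the number of arrays and not the number of genes. For NF-kappaB and inflammatory targets the estimate (0.0086) lay below 0.01, yet the unadjusted camera p rose from 0.307 to 0.357. The loss of the list calls therefore cannot be put down to the correlation alone. Among the lists called at the preset 0.01, the estimates ran from 0.045 for p53 target genes to 0.66 for fatty acid oxidation and ketogenesis. Fry, which asks a different question, called 10 higher. Single genes were set against the alternatives with each gene counted once per setting, so the counts are pairs of gene and setting. Of these pairs, 123 lost the call, 21 gained it and 5285 kept their result. With a mouse left out, 610 pairs lost the call, 7 gained it and 2108 kept their result, and 0 turned. No paired analysis was possible because the genotypes share no replicate number. Without detection calls, signal over background is unknown, so the changes of dim genes are understated by an unknown amount.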

Other observations

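The tests of the gene lists and explanations below were all chosen after the values were seen, and so were the genes named with them. Immediate-early genes, which respond within minutes to growth factors and stress, were mostly higher in knock-in liver. Of 36 measured, 23 were called higher and 2 lower (24 and 2 adjusted over the list alone), with a median log2 change of 0.92 (camera adjusted p = 2.00e-11 over 2 lists, and adjusted p = 0.0572 with an estimated correlation, or adjusted p = 0.0259 once knock-in replicate 5 was left out). Besides Btg2 and Nr4a1, Gadd45b rose 8.42-fold, Myc 7.16-fold, Nr4a3 4.85-fold, Maff 4.81-fold and Jun 3.62-fold. Fos changed by 0.27 ± 0.09 and did not pass (limma adjusted p = 0.0561), and Klf10 and Ccn1 were lower. Of the 36 members, 8 are also in the lists fixed beforehand.

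Complement and coagulation genes, made mainly by hepatocytes, leaned the other way. Of 43 measured, 18 were called lower and 2 higher (22 and 2 adjusted over the list alone), with a median log2 change of -0.47 (camera adjusted p = 2.89e-05, and adjusted p = 0.361 with an estimated correlation). The terminal complement gene C9 was 5.00-fold lower, Mbl1 was 3.74-fold lower and F11 2.81-fold lower, while the anticoagulant gene Pros1 was 2.58-fold higher and Kng2 1.25-fold higher. The call of Kng2 was lost without each mouse but knock-in replicate 5 (adjusted p = 0.0582 to 0.109). The fibrinogen genes Fga, Fgb and Fgg did not pass, with log2 changes of -0.06, 0.09 and 0.06. Of the 43 members, 12 are also in the lists fixed beforehand. Without knock-in replicate 5 the median was -0.29, and without knock-in replicate 1 or wild-type replicate 2 the number called lower was 10. Both directions stayed with pseudocounts of 1 and 64, quantile normalization and centred arrays.

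The clock genes may differ because the livers were taken at different times of day. Genes that peak late in the night (Arntl, Clock, Cry1 and Nfil3) had a median log2 change of 2.42, and 12 genes that peak between day and dusk had a median of -0.57, a difference of 2.99. These groups of genes were set after the values were seen, so the difference describes the pattern and does not test the explanation. Per1, which also responds to glucocorticoids, went against its group, rising by 1.15. With no sampling times on the labels, time of day and an effect of the genotype on the clock cannot be told apart, and both stay open.

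Fat oxidation and fat synthesis genes fell together. By the labels every mouse went 6 h without food, so a longer fast would be a departure from them. A longer fast in the knock-in mice is argued against as the cause of the fall of the fat oxidation genes. A fast induces most of them, and their median log2 change was -1.02 with an upper quartile of -0.65. Ppara, which drives them, also fell, so their fall cannot show whether the fast was longer. Some genes that a fast induces were higher (Igfbp1 3.12, Ppargc1a 2.30 and, within the fat oxidation list, Pdk4 1.67, with Tat at 0.60 and Pck1 at 0.29, calls that single mice ended, and Lpin1 at 1.04, not passing), and the fall of glycolysis and lipogenesis genes (median -0.68, upper quartile -0.11) is part of the pattern itself, so beyond the fat oxidation genes a longer fast stays open. A lower share of hepatocytes would lower hepatocyte identity genes by about as much, and their lower quartile was -0.29 (median -0.07). Of the 24 measured, 6 were called lower and 3 higher, so they did not fall as a set. Some, such as Alb (17659 in knock-in and 17221 in wild-type liver), lay among the brightest signals, where a change may be compressed. Markers of other liver cells, whose share would then be larger, had medians of -0.30 (Kupffer cells and macrophages), -0.20 (endothelial), -0.11 (stellate) and 0.03 (cholangiocytes). Neutrophil markers had a median of 0.24. These values argue against a lower share of hepatocytes as the whole cause of the fall of the fat oxidation genes. A smaller drop in that share stays open. Effects of the genotype on fat metabolism remain open and were not tested.

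Knock-in replicate 3 lay between the other knock-in mice and wild-type. A wild-type sample under a knock-in label is argued against, since its lowest correlation with a knock-in array exceeded its highest with a wild-type array by 0.00829 (0.988 against 0.980). Over 189 probe sets at least 4-fold lower in the other 2 knock-in mice and at 400 or more in wild-type, the median share of the way to wild-type was 0.165 (5th to 95th percentile -0.000168 to 0.464), and wild-type RNA mixed in at that share would lift each of them to at least 0.165 of its wild-type level. Against this, 17 read below 0.165 of the lowest wild-type mouse, 5 of them by over 2 SD (SD 0.0431, from the spread between the other 2), with Dio1 at 111 against 1881 and Inhbe at 51 against 818. Over 98 probe sets at least 4-fold higher in the other 2 knock-in mice, the median share was 0.361. Mixing as the whole cause is thus argued against, while a smaller admixture (at most 0.0590 by the Dio1 reading) stays open. That limit counts the whole reading as wild-type RNA. Above the level of the other 2 knock-in mice, the share was 0.029 for Dio1, 0.002 for Inhbe and 0.003 for Anks4b, against 0.189 for Fabp1. A milder response of that mouse stays open as untested.

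Of the 10 splits of the 6 arrays into groups of 3, 1, the real one, gave 6888 calls, and the highest of the others gave 0, with at most 1269 probe sets at an unadjusted limma p below 0.05. With 10 splits the share cannot fall under 0.1. Each of the other splits puts mice of both genotypes in both groups. The genotype difference then adds to the spread within groups and lowers the calls, so the 0 does not measure a rate of false calls.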
